A study of Homo sapiens with 4 samples.

How the data were processed

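RNA of 4 samples of Kit225 cells was measured on Affymetrix HG-U133 Plus 2.0 arrays, 2 samples treated with NC1153 and 2 with DMSO, all for 12 hours per the labels. Samples were grouped by their titles, which also give a replicate number. Nothing states whether replicates came from separate cultures, so p-values here measure only the spread between these samples, which may be technical.

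The deposited values of the whole array are intensities on a linear scale for 54675 probe sets, of which 62 are controls. They have the form of globally scaled signals: the mean after trimming 2% at each end lay between 499.919 and 499.921 on each array, and no value was 0 or negative. Per the file headers of a second table, the arrays were scaled by factors of 6.68 (NC1153 replicate 1), 2.88 (DMSO replicate 1), 2.97 (NC1153 replicate 2) and 2.66 (DMSO replicate 2), so NC1153 replicate 1 was the dimmest array before scaling. The software and version behind the signals are not given in the sources used here, and no detection calls were used. The second table holds log2 values for 2252 probe sets that the authors obtained by RMA and selected with limma and Storey q-values at a limit of 0.05, per the file headers. It also holds the authors' raw p-value of each of these probe sets. Since it is a selection, it served only as a comparison.

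The design written before the data were examined assumed RMA log2 values for the whole array. The values were linear, so log2 of the signal was taken, as that design allowed, with no pseudocount. Low signals are noisy on this scale: a signal can fall to 0.143, and the number of arrays limits the precision of every value.

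Differences were fitted with lmFit and eBayes (trend=TRUE) of limma 3.58.1 in R 4.3.3, NC1153 minus DMSO, over the 54613 non-control probe sets, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. All tests were two-sided. The fit has 2 residual degrees of freedom per probe set and borrowed 7.27 prior degrees of freedom from all probe sets. Every adjusted p of a gene in the text is from this limma fit unless another setting is named. A signal is given as mean ± SD, and a change as a log2 difference of group means.

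Probe sets were named through the platform annotation, with symbols updated by gene identifier from an NCBI RefSeq gene table (GRCh38.p14), which was used for names only. Of the tested probe sets, 41091 were listed with 1 gene, 1801 with several and 11721 with none. Symbols of 41037 were matched in the newer table, and 54 kept their old symbol. Only probe sets with 1 gene were named. Each of the 19775 genes was represented by its probe set with the highest mean over the 4 arrays, and for named genes past the threshold another probe set of opposite sign is mentioned.

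Before the data were examined, 33 gene lists and the rule for named genes were fixed. The rule took the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose NC1153 arrays both lay on the same side of both DMSO arrays and whose higher group mean exceeded the median of all values. It further took up to 4 members per list past the threshold, or 2 as values where none passed, and always JAK3, STAT5A, STAT5B, IL2RG, IL2RA, CISH, PIM1, BCL2, MYC and CCND2. Lists were tested with camera of limma at its preset correlation of 0.01, adjusted over the 33 lists. Of the 819 list entries, 723 were measured.

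The replicate number was checked as a pairing. Across probe sets, deviations of equally numbered arrays from their group means correlated with r = 0.055 over all probe sets, 0.12 over the brighter ones and 0.21 in the authors' RMA table, and array names in the header of the authors' table share a number within each replicate. The labels do not say that the numbers mark a shared batch. The fit without the number is therefore the main one, and the fit with it as a block stands beside the counts it moves.

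The fit was first tested on simulated data of 54613 probe sets, with 200 changed ones among the brighter probe sets. These data had the real means, independent normal noise and variances drawn from the fitted prior. They follow the variance model of the fit and so cannot test whether that model holds for the arrays. The fit called 5% of the probe sets changed by 1 on the log2 scale and 48% of those changed by 2. Of its calls, 7.02% were false. The median fitted changes were 1.05 and 2.04. In a second simulation with independent genes, camera with the preset correlation called 100% of 20 lists shifted by 0.5 and 0% of the unshifted ones. With an estimated correlation it called 0% of the shifted lists, and fry called 30% of them.

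Alternatives fixed before the data were examined covered the variance model, normalization, filters, probe set choice, the threshold, the replicate block, other list tests and leaving out each array. Others were added afterwards: log2(signal + 50), quantile normalization together with the filter on dim probe sets, the authors' RMA values, and centring on spiked-in controls. The last centred each array on the mean log2 signal of 18 spiked-in control probe sets (bioB, bioC, bioD and cre). These are hybridisation controls, so centring on them does not measure RNA per cell. Plots were drawn with matplotlib 3.10.9.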

Results

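Kit225 cells, a human leukemic T cell line that depends on interleukin-2 (IL-2) for growth, were kept in medium with IL-2 and exposed to NC1153, a compound described as an inhibitor of JAK3 signalling, or to its solvent DMSO. Exposure lasted 12 hours. The labels give the dose as 25 mM NC1153 against 0.1% DMSO, and the unit of that dose could not be checked here. Each condition has 2 arrays, numbered 1 and 2. Median signals were 88.6 and 61.8 on the NC1153 arrays and 69.7 and 69.5 on the DMSO arrays. The 18 probe sets of spiked-in bacterial and phage controls were 1.16- to 1.58-fold higher with NC1153, 17 of them within both replicates (median log2 change 0.57 within replicate 1 and 0.33 within replicate 2). Among the 27306 brighter probe sets, the SD of the log2 difference was 0.57 between the DMSO arrays and 0.72 between the NC1153 arrays, against 0.71 to 0.86 between arrays of different conditions.

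The comparison asks which transcripts differed after 12 hours of NC1153. DDIT3, which encodes the stress transcription factor CHOP, rose from a signal of 268 ± 92.7 to 3589 ± 41.5 (SD, n = 2 each), a log2 change of 3.79. IL2RB, the IL-2 receptor beta chain, fell from 6953 ± 752 to 1024 ± 109 (SD, n = 2 each), a log2 change of -2.76. The phosphatase gene DUSP6, which restrains ERK, changed by -2.87. By the list test camera at its preset correlation, lists of ATF4 and NRF2 target genes were higher with NC1153. Lists of ribosome biogenesis and MYC target genes, of DNA replication genes and of IL-2 target genes were lower. Part of each list did not pass. All of these list calls were lost with an estimated correlation (adjusted p = 0.20 to 0.21). In the simulation that setting also called 0% of the lists shifted by 0.5, whose genes were independent. Larger shifts and correlated genes were not simulated. Whether such a loss comes from low power or from correlation between the members of a list therefore stays open. In all, limma called 1062 probe sets higher and 971 lower, and 8653 had an unadjusted p under 0.05. By gene, 612 were higher and 562 lower, of which 288 and 264 differed at least 2-fold.

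These counts depend on the variance model. Without a trend in the prior variance limma called 0 probe sets, with 5300 at an unadjusted p under 0.05, and an ordinary test per probe set also called 0, with 6110 at that level. Centring each array on its median left 23 higher and 24 lower. Centring on the spiked-in controls, a setting chosen after seeing the data and called spike-in centring below, left 85 higher and 1019 lower. Of 95 named genes past the threshold 38 lost the call, 35 of them rises. This setting moved the median log2 change of all probe sets from 0.022 to -0.41, so list medians with spike-in centring are to be read against -0.41. With the replicate number as a block, 2061 were higher and 1936 lower, among them all 2033 of the calls without it. All 2033 had the same sign within replicate 1 and within replicate 2, a condition that their selection favours. Without NC1153 replicate 1, the array with the largest scaling factor, 487 were higher and 643 lower, and 998 of the 2033 calls remained.

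**Figure D1:**
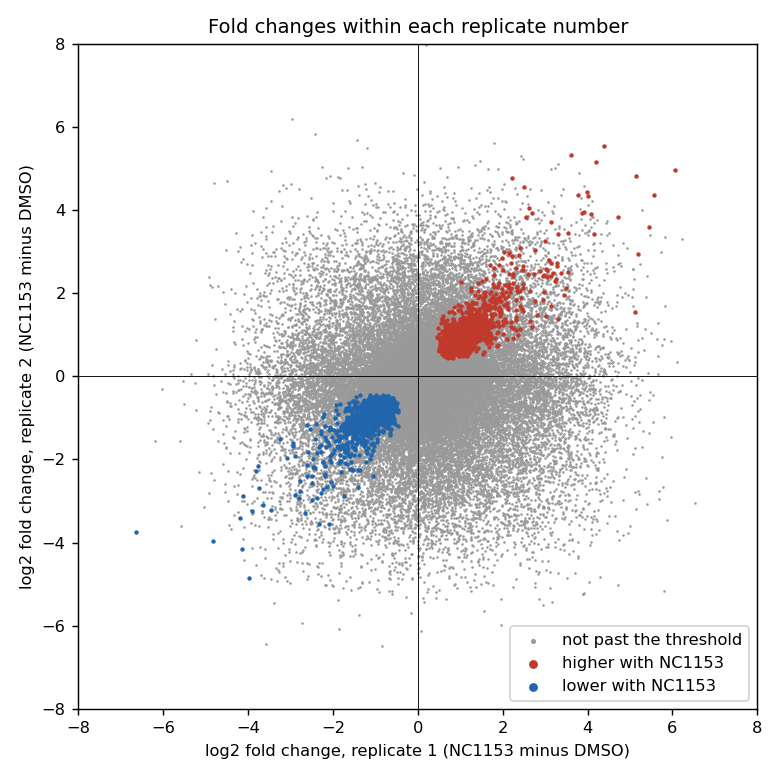
Each point is a probe set, with its log2 fold change (NC1153 minus DMSO) between the replicate 1 arrays on the x axis and between the replicate 2 arrays on the y axis; red and blue mark probe sets with an adjusted p under 0.05. The 1062 higher and 971 lower probe sets lie in the upper right and lower left, while the correlation was 0.093 across all probe sets and 0.42 across the brighter ones.

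The authors' deposited table lists 2252 probe sets, 1331 higher and 921 lower with NC1153. Of the 2250 that are not controls, 2237 had the same sign in the signals used here, 1425 were called in that direction and 2077 had an unadjusted p under 0.05. A further 608 calls made here are not in the authors' deposited table. Both rest on the same 4 arrays, so their overlap is no independent evidence.

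Among 28 IL-2 and STAT5 target genes, 9 fell, 1 rose and 18 did not pass. Besides IL2RB and DUSP6, LIF, a cytokine of the IL-6 family, fell by 1.77 on the log2 scale, and SOCS1, a feedback inhibitor of JAK kinases, fell by 1.71. CISH, another STAT5-induced feedback inhibitor, fell by 0.96 (adjusted p = 0.027), with all of its other probe sets also called lower. The kinase gene PIM1 changed by -1.06 (adjusted p = 0.0087) and the cyclin gene CCND2 by -0.66 (adjusted p = 0.023). BCL2, an inhibitor of apoptosis that the list also holds, went the other way, from 1379 ± 77.9 to 3292 ± 97.2 (SD, n = 2 each), a log2 change of 1.26 (adjusted p = 0.0030; 0.83 and adjusted p = 0.083 with spike-in centring). The list was lower as a whole (median -0.64, camera adjusted p = 3.5e-06; adjusted p = 0.21 with an estimated correlation). Adjusted over the list alone, 13 fell and 2 rose. Of the 13 lists that passed camera, 8 higher and 5 lower, 0 passed with an estimated correlation and 9 with the rotation test fry. The CCND2 call was lost without DMSO replicate 1 (adjusted p = 0.32) and without DMSO replicate 2 (adjusted p = 0.17).

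The genes of the receptor and kinase themselves mostly did not pass. JAK3 had a log2 change of -0.67 (adjusted p = 0.20), STAT5A -0.25 (adjusted p = 0.78), STAT5B 0.11 (adjusted p = 0.81), IL2RG -0.13 (adjusted p = 0.84) and IL2RA -0.01 (adjusted p = 0.99). Of the 3 other JAK3 probe sets, 2 had the opposite sign. MYC had a log2 change of -0.75 (adjusted p = 0.12). With the replicate block JAK3 passed (adjusted p = 0.034) and so did MYC (adjusted p = 0.0065). The DMSO arrays differed for MYC, with signals of 7304 and 12786 on replicates 1 and 2 against 5919 and 5606 with NC1153. Without DMSO replicate 1 its log2 change was -1.15. Of 24 JAK-STAT pathway components, IL2RB fell and JAK1 rose, by 0.65. Adjusted over the list alone, 2 rose and 2 fell, and the list did not pass (camera adjusted p = 0.55; lower at 0.014 with spike-in centring). The JAK1 call was lost without NC1153 replicate 1 (adjusted p = 0.087), DMSO replicate 1 (adjusted p = 0.12) or DMSO replicate 2 (adjusted p = 0.24), and with spike-in centring (adjusted p = 0.59).

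**Figure D2:**
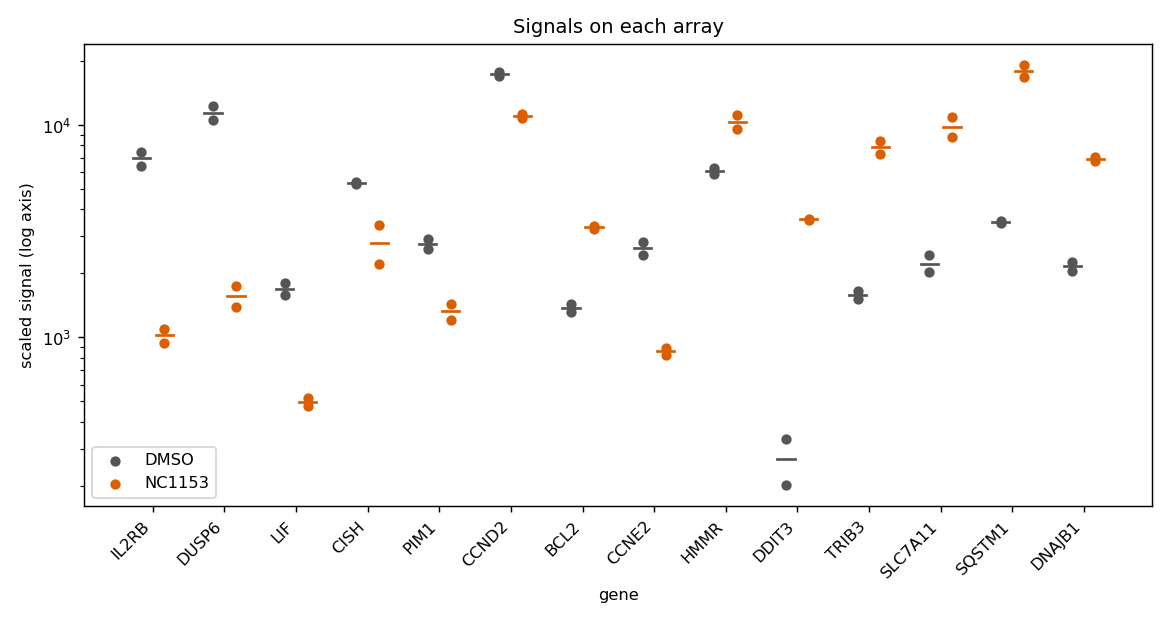
Scaled signals on a log axis for 14 named genes on each of the 2 DMSO arrays (grey points) and 2 NC1153 arrays (orange points), with bars at the means. IL2RB and DUSP6 lie lower with NC1153, while DDIT3 lies higher, at 3589 against 268 on average.

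Cell cycle genes moved in both directions. Of 36 G1/S and DNA replication genes, 14 fell, 1 rose and 21 did not pass. The cyclin gene CCNE2 fell by 1.61 on the log2 scale, the helicase subunit gene MCM7 by 1.47, the DNA methylation factor gene UHRF1 by 1.44 and the flap endonuclease gene FEN1 by 1.28. The list was lower (median -0.58, camera adjusted p = 1.9e-14; adjusted p = 0.20 with an estimated correlation), and adjusted over the list alone 23 fell and 1 rose. Of 30 G2/M and mitosis genes, 6 rose and none fell. CDC25C, an activator of CDK1, rose by 1.49, HMMR by 0.77, KIF23 by 0.76 and the checkpoint kinase gene TTK by 0.74. That list was higher (median 0.35, camera adjusted p = 1.7e-07; adjusted p = 0.20 with an estimated correlation), and adjusted over the list alone 15 rose and 1 fell. Leaving out single arrays ended the calls of HMMR (adjusted p up to 0.10), KIF23 (up to 0.17) and TTK (up to 0.13). With spike-in centring the G2/M list did not pass (median -0.079, adjusted p = 0.11), nor did CDC25C (0.064), HMMR (0.48), KIF23 (0.48) and TTK (0.51). Of 19 replication-dependent histone genes, H2AC8 and H2BC3 rose by 4.21 and 3.42 from DMSO signals of 7.35 and 21.3. The median of the histone list was 0.52 (camera adjusted p = 0.030; adjusted p = 0.69 with an estimated correlation), with 4 higher adjusted over the list alone. It did not pass without NC1153 replicate 2 (adjusted p = 0.64) or without DMSO replicate 1 (adjusted p = 0.19).

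Stress response genes were among those that rose. Of 32 ATF4 and CHOP target genes, 21 rose, none fell and 11 did not pass. After DDIT3 came TRIB3, a pseudokinase that restrains ATF4, with a log2 change of 2.30, the transcription factor gene ATF3 with 2.16 and the cystine transporter gene SLC7A11 with 2.14. The list median was 0.90 (camera adjusted p = 8.1e-24; adjusted p = 0.20 with an estimated correlation), and adjusted over the list alone 26 rose and 1 fell. Of 26 NRF2 targets and glutathione genes, 10 rose, none fell and 16 did not pass. SQSTM1, the autophagy receptor p62, rose by 2.36, AKR1C1 by 1.89 and SRXN1, which repairs peroxiredoxins, by 1.86. The NRF2 list had a median of 0.71 (camera adjusted p = 1.3e-10; adjusted p = 0.20 with an estimated correlation), with 15 higher adjusted over the list alone. SLC7A11 belongs to both of these lists. The AKR1C1 call was lost without NC1153 replicate 1 (adjusted p = 0.067) or NC1153 replicate 2 (adjusted p = 0.069), and with spike-in centring (adjusted p = 0.11).

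Among 22 heat shock and cytosolic chaperone genes, 5 rose, with HSPA1L at 2.77, DNAJB4 at 2.74, DNAJB1 at 1.68 and the co-chaperone gene BAG3 at 1.22. HSPA1L rose from a DMSO signal of 56.9, below the median of all signals, 72.3. Its RMA change by the authors was 1.23, against 3.42 for DNAJB4, 1.65 for DNAJB1 and 1.27 for BAG3. The list members HSPA1A and HSPA1B were not measured. Most members did not pass, and the list median was 0.28 (camera adjusted p = 0.011; adjusted p = 0.35 with an estimated correlation), with 7 higher and 1 lower adjusted over the list alone. Of 11 metallothionein and zinc transport genes, MT1X, MT2A and MT1E rose by 2.42, 1.97 and 1.38, and the zinc importer gene SLC39A10 fell by 1.47. Its list median was 1.10 (camera adjusted p = 0.023; adjusted p = 0.69 with an estimated correlation), with 7 higher and 1 lower adjusted over the list alone. Of 25 lysosome and autophagy genes, 5 rose, among them SQSTM1, MAP1LC3B at 1.57 and HEXA at 1.06, and LAMP2 fell by 0.85, although its 3 other probe sets had the opposite sign. The list median was 0.34 (camera adjusted p = 8.5e-06; adjusted p = 0.35 with an estimated correlation), with 8 higher and 1 lower adjusted over the list alone. Of 22 endoplasmic reticulum chaperones and unfolded protein response genes, 5 rose, including HERPUD1 at 1.33, DNAJB9 at 1.22, ERN1 at 1.12 and XBP1 at 0.88, and both other probe sets of ERN1 had the opposite sign. Adjusted over the list alone 5 rose, and the list did not pass (camera adjusted p = 0.061), but it passed with quantile normalization (0.037), the replicate block (0.044), without NC1153 replicate 1 (0.0053) and without DMSO replicate 1 (0.0064). The metallothionein list no longer passed without NC1153 replicate 1 (adjusted p = 0.24), and leaving out single arrays ended the calls of HSPA1L (adjusted p up to 0.083), ERN1 (up to 0.12), MT1X (up to 0.22), MT2A (up to 0.16), MT1E (up to 0.16), HEXA (up to 0.064) and LAMP2 (up to 0.080). Spike-in centring ended the call of the heat shock list (median -0.15, adjusted p = 0.12) and of BAG3 (0.10), MT1X (0.081), MT2A (0.066), MT1E (0.16), HEXA (0.24), HERPUD1 (0.053), DNAJB9 (0.11), ERN1 (0.27) and XBP1 (0.43), and the median of the lysosome list, which still passed, was -0.089.

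**Figure D3:**
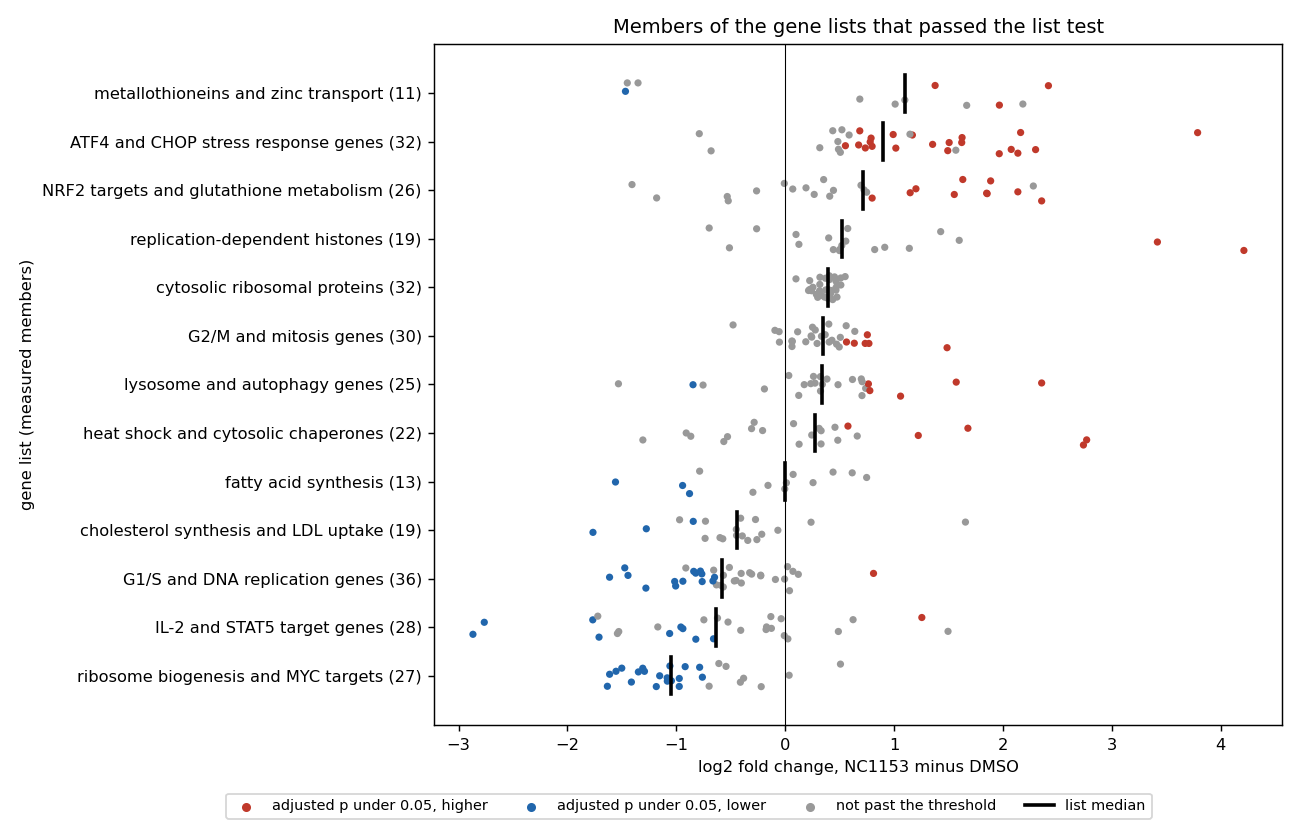
Log2 fold changes (NC1153 minus DMSO, x axis) of the members of the 13 lists that passed camera with its preset correlation, 1 point per gene and a black bar at each median; red and blue mark members with an adjusted p under 0.05. Medians run from -1.04 for ribosome biogenesis and MYC targets to 1.10 for metallothioneins and zinc transport. None of these lists passed camera with an estimated correlation, where the lowest adjusted p was 0.20. That setting also called 0% of the lists of independent genes shifted by 0.5 in the simulation, where larger shifts were not tried.

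The list of ribosome biogenesis genes and MYC targets had the largest share of falling members. Of 27 measured genes, 19 fell and none rose. RRP12 fell by 1.63 on the log2 scale, RRP9 by 1.61, and UTP20 by 1.55, and CAD, which encodes the enzyme that starts pyrimidine synthesis, also fell. The median was -1.04 (camera adjusted p = 3.2e-21; adjusted p = 0.20 with an estimated correlation), and 22 fell adjusted over the list alone. The 32 genes of cytosolic ribosomal proteins all had positive log2 changes, between 0.10 and 0.55, but limma called 0 of them, 0 adjusted over the list alone, and 8 had an unadjusted p under 0.05. RPS24 had a value of 0.55 and RPL3 of 0.51. Both passed without NC1153 replicate 2 (adjusted p = 0.0094 for each), RPS24 also with the replicate block (adjusted p = 0.035), and another RPS24 probe set has the opposite sign. The list passed camera (median 0.39, adjusted p = 4.5e-06; adjusted p = 0.69 with an estimated correlation). It did not after quantile normalization (median 0.0075, adjusted p = 0.96) or with spike-in centring (median -0.039, adjusted p = 0.085), and its median was 0.66 within replicate 1 and 0.15 within replicate 2.

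Lipid synthesis genes were partly lower. Of 19 cholesterol synthesis and uptake genes, INSIG1, SQLE and MSMO1 fell, by 1.77, 1.28 and 0.84 on the log2 scale, and 16 did not pass. The list median was -0.45 (camera adjusted p = 2.7e-06; adjusted p = 0.45 with an estimated correlation), with 8 lower adjusted over the list alone. Of 13 fatty acid synthesis genes, FASN, SCD and ACSL1 fell by 1.56, 0.94 and 0.88, with 4 lower adjusted over the list alone. The fatty acid list had a median of -0.0033 and a mean of -0.19 (camera adjusted p = 0.045; adjusted p = 0.45 with an estimated correlation). It did not pass without NC1153 replicate 1 (adjusted p = 0.062) or without NC1153 replicate 2 (adjusted p = 0.12). Of 31 glycolysis and hypoxia response genes, ANKRD37 fell by 2.29, the hexokinase gene HK2 by 1.78 and PFKFB3 by 0.92, and MXI1 rose by 0.95. Adjusted over the list alone 4 fell and 1 rose, and that list did not pass (camera adjusted p = 0.15), but it passed with quantile normalization (0.037), without NC1153 replicate 1 (0.028) and without DMSO replicate 2 (0.0024). Calls lost on leaving out single arrays were those of MSMO1 (adjusted p up to 0.18), FASN (up to 0.059), ACSL1 (up to 0.054), PFKFB3 (up to 0.24) and MXI1 (up to 0.11). With spike-in centring MSMO1 (adjusted p = 0.061), PFKFB3 (0.054) and MXI1 (0.23) did not pass, and the glycolysis list did (0.0026).

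Several T cell genes changed. The chemokine receptor genes CCR6 and CCR7 fell by 2.83 and 2.73 on the log2 scale, S1PR1, a receptor for exit from lymph nodes, by 1.81 and its regulator KLF2 by 1.80. BCL6 rose by 1.34. Of 18 FOXO targets and resting T cell genes, 6 rose and 3 fell, the same numbers as adjusted over the list alone, and the list did not pass (camera adjusted p = 0.26). The adaptor gene LCP2 fell by 2.15 and the kinase gene FYN rose by 0.95, the calls among 23 T cell receptor and identity genes (camera adjusted p = 0.061), of which 7 fell and 1 rose adjusted over the list alone. Of 31 cytokine and cytokine receptor genes, CCR6 and CCR7 were those called, and 2 adjusted over the list alone (camera adjusted p = 0.16). Of 10 phosphodiesterase genes, PDE4B fell by 1.15, PDE7A by 0.82 and PDE4A by 0.77, and PDE8A rose by 0.80, with 3 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.16). The T cell receptor list passed without dim probe sets (0.027), with the replicate block (0.044), without NC1153 replicate 1 (0.028) and without DMSO replicate 2 (0.019), and the cytokine list without dim probe sets (0.016) and without DMSO replicate 2 (0.020). With single arrays left out, the calls of KLF2 (adjusted p up to 0.10), BCL6 (up to 0.097), FYN (up to 0.11), PDE7A (up to 0.25), PDE8A (up to 0.17) and PDE4A (up to 0.18) were lost, that of PDE8A with each of the 4 arrays, and spike-in centring ended those of BCL6 (0.21), FYN (0.30) and PDE8A (0.47).

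Among 21 p53 target genes, SESN2, FAS, which encodes a death receptor, and SESN1 rose by 1.63, 1.58 and 0.96 (list camera adjusted p = 0.25; 0.0205 without DMSO replicate 2), with 6 higher and 2 lower adjusted over the list alone. SESN2 is also a member of the ATF4 and CHOP list, and SESN1 of the FOXO list. Of 24 BCL2 family and caspase genes, BCL2 and CASP8 rose, the latter by 0.88. Adjusted over that list alone 4 were higher (camera adjusted p = 0.49). Of 23 immediate early genes, 3 rose and 2 fell. The rises of MAFF and JUN were 2.19 and 1.35, and JUNB and IER3 fell by 1.33 and 1.29. Adjusted over the list alone, 3 rose and 3 fell. That list had a median of 0.19 and a mean of -0.02 and did not pass (camera direction lower, adjusted p = 0.86). Of 29 interferon-stimulated genes, GBP2 and IRF9 rose by 1.43 and 1.11, with 4 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.53). Of 27 proteasome subunit genes, PSMD4 rose by 0.67, also the 1 gene called adjusted over the list alone (camera adjusted p = 0.21; 0.017 with the mean of all probe sets of a gene). SESN1 (adjusted p up to 0.10), MAFF (up to 0.15), JUN (up to 0.073), IRF9 (up to 0.059) and PSMD4 (up to 0.25) lost their calls on leaving out single arrays, SESN1 with each of the 4. Spike-in centring ended the calls of SESN1 (adjusted p = 0.35), CASP8 (0.26), MAFF (0.12), JUN (0.088), GBP2 (0.10), IRF9 (0.25) and PSMD4 (0.55).

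In 3 further lists limma called 0 genes, and 0 adjusted over each list alone. These were 23 NF-kB target genes (1 higher and 4 lower at an unadjusted p under 0.05, camera adjusted p = 0.31), 15 cytotoxic granule and effector genes (1 higher and 2 lower, camera adjusted p = 0.96) and 26 oxidative phosphorylation subunit genes (2 higher and 3 lower, camera adjusted p = 0.86). In the last of these, ATP5MC1 at -0.62 (adjusted p = 0.062) passed with the replicate block (adjusted p = 0.0092), without dim probe sets (0.028) and with 1 probe set per gene (0.020). Its log2 change was -0.79 without DMSO replicate 2. That of SDHD was -0.45 with all arrays and -0.60 without NC1153 replicate 2. With spike-in centring ATP5MC1 (0.040) and the oxidative phosphorylation list (lower, 0.0029) passed. The list median was then -0.40 against -0.41 over all probe sets, so the list fell no further than the array as a whole. Marker lists of other cell types were tested for a difference between the conditions, which cannot show whether such cells were present in both. B cell (camera adjusted p = 0.87), myeloid (0.90), erythroid and platelet (0.69), fibroblast and epithelial (0.58) and natural killer cell markers (0.95) did not pass. Among them limma called 1 gene, PPBP, which rose by 1.11 from a DMSO signal of 267, and that call was lost without each of the 4 arrays (adjusted p up to 0.14) and with spike-in centring (adjusted p = 0.37). COL1A1 was not called (1.77, adjusted p = 0.21), and its log2 change was 2.70 without DMSO replicate 2. Its DMSO signals were 30.9 and 111 on replicates 1 and 2. The myeloid list had a median of -0.19 and a mean of 0.14, and the natural killer list a median of 0.20 against a camera direction of lower.

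The largest falls by the naming rule were those of HCP5, at -3.80 on the log2 scale, the vesicle transport gene RAB27B at -3.33, RIBC2 at -3.21, GAS1 at -2.96 and the phosphoinositide kinase gene PIK3CG at -2.93. Those of HPDL at -2.87, DUSP6, CCR6, IL2RB, CCR7, the TNF family gene TNFSF14 at -2.66 and the transporter gene SLCO4A1 at -2.65 followed. All 12 are also in the authors' deposited table, with RMA log2 changes of -3.77 to -0.93. For 4 of them, HCP5, RIBC2, GAS1 and TNFSF14, the mean NC1153 signal lay below the median of all signals, 72.3. The size of these falls therefore rests on signals near background, and their RMA changes were -2.91, -1.03, -0.93 and -1.31. The largest rises were those of the histone gene H4C1 at 4.96, H2AC8, MUC12 at 4.18, RGS22 at 4.08, PKD1P1 at 4.06, LOC100996756 at 3.94, DMGDH at 3.90, DDIT3, ATP6AP1L at 3.49, H2BC3, CDKL3 at 3.32 and MST1 at 3.20. Of these 12 genes, 10 had a mean DMSO signal below the median of all signals, 72.3, so their fold changes rest on signals near background. MUC12 and ATP6AP1L each have another probe set of opposite sign, at -2.37 and -1.94. The authors' deposited table holds 8 of the 12 with smaller RMA changes, among them MUC12 at 0.61, RGS22 at 0.69, H2AC8 at 1.13, PKD1P1 at 1.32, ATP6AP1L at 1.535, LOC100996756 at 1.59 and DDIT3 at 2.86. Another probe set of opposite sign exists also for SOCS1, JAK1, CDC25C, SQSTM1, HSPA1L, HEXA, RRP12, FASN, FYN, PDE4A, PSMD4, GAS1 and CDKL3. Of the 63 named genes past the threshold that have other probe sets, 16 had all of them called the same way. With log2(signal + 50), a setting chosen after seeing the data, 7 of the 12 rises and 11 of the 12 falls remained past the threshold. Leaving out single arrays ended the calls of H4C1 (adjusted p up to 0.13), H2AC8 (up to 0.12), MUC12 (up to 0.10), RGS22 (up to 0.14), PKD1P1 (up to 0.14), LOC100996756 (up to 0.13), DMGDH (up to 0.17), H2BC3 (up to 0.12), MST1 (up to 0.11), GAS1 (up to 0.36) and TNFSF14 (up to 0.12). Spike-in centring ended those of H2AC8 (0.077), RGS22 (0.062), PKD1P1 (0.052), LOC100996756 (0.074), DMGDH (0.087), H2BC3 (0.063), MST1 (0.058) and GAS1 (0.055).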

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

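Control probe sets for 28S ribosomal RNA, left out of the gene comparisons, gave higher signals with NC1153. Their tests were chosen after the results were seen. The middle one was 9.43-fold higher (mean signal 9727 against 1038). The 5' one was 2.48-fold higher (6311 against 2240), but 1.21-fold within replicate 1 and 5.08-fold within replicate 2. The 3' one had low signals (62.8 against 17.4) and no test. It was 2.71-fold higher, 5.68-fold within replicate 1 and 1.29-fold within replicate 2. Rescaling of the dim NC1153 replicate 1 array is argued against for the middle probe set, since its log2 rise was 3.15 within replicate 1 and 3.33 within replicate 2, a ratio of 1.06. A general carry-over of ribosomal RNA would raise 18S as well: the median log2 rise of 18S was 0.167 of that of the middle probe set, which argues against it there, but 0.41 of that of the 5' probe set (bounds 0.25 and 0.5), so for that one it stays open. Degraded RNA is not favoured either, with a GAPDH 3' to 5' ratio 0.997 times that with DMSO. An effect of NC1153 on 28S RNA stays open as well and had no test of its own here, and the arrays carry few probes for this RNA.

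The large rises of named genes, 10 of 12 with a DMSO signal under the median of 72.3 (not DDIT3 at 268 and CDKL3 at 90.7), were weighed against noise near background and against rescaling of NC1153 replicate 1; the setting log2(signal + 50) and the values without that array were chosen after the results were seen. With log2(signal + 50), 7 of the 12 rises stayed past the threshold, between the bounds set before the test was run (fewer than 6 for noise, at least 9 against it), and 5 of the 10 with low signals did, with smaller RMA values by the authors for 6 of those (0.61 to 1.59), so noise stays open for the low signals. Among all dim probe sets, 4-fold rises outnumbered 4-fold falls within replicate 1 (4432 against 2897) but not within replicate 2 (2509 against 3946, a ratio of 0.636), which meets the bound set beforehand for rescaling (at most 1). Without NC1153 replicate 1 the log2 rises of the 12 genes were 3.21 to 4.42, with a median 0.994 times that with all arrays, but both NC1153 arrays had to lie above both DMSO arrays for a gene to be selected, so this does not decide and rescaling stays open. Treatment with NC1153 also remains a possible explanation.

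The small positive changes of all 32 ribosomal protein genes may come from the scaling. Their median of 0.39 lay at the 98.1 percentile of 10000 random lists matched on signal level (central 95% 0.19 to 0.38, median 0.30), but these lists ignore that the members move together (correlation 0.99), so a part beyond level is not shown. After quantile normalization the median was 0.0075 (adjusted p = 0.96), and after centring on the spiked-in controls, added after seeing the data, -0.039 (adjusted p = 0.085). Within replicate 2 the median was 0.228 times that within replicate 1, under the bound of 0.5 set for rescaling of the dim array. Both explanations stay open, and no effect of NC1153 on these genes can be claimed.

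The 18 probe sets of spiked-in controls were 1.16- to 1.58-fold higher with NC1153, 17 of them within both replicates. Centring on them left 85 probe sets higher and 1019 lower. As hybridisation controls they do not show whether the RNA content of the cells changed.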

How the results depend on the processing

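Settings named as added were chosen after seeing the data; the others were fixed before. No result past the threshold changed its tested direction under any setting run. The median of the fatty acid list, -0.0033, was 0.0032 without NC1153 replicate 2. Spike-in centring turned some list medians below 0, while it moved the median of all probe sets to -0.41. The main counts were 1062 probe sets higher and 971 lower. They were 0 and 0 without a variance trend (5300 at an unadjusted p under 0.05) and 0 and 0 by the ordinary test (6110). Centring on array medians gave 23 and 24, and on the spiked-in controls (added) 85 and 1019. Leaving out dim probe sets gave 1722 and 1587, with quantile normalization as well (added) 1675 and 1661, without cross-hybridising probe sets 559 and 524, and at an adjusted p under 0.01 259 and 280; other settings stayed within 1.5 times. With the replicate block they were 2061 and 1936; deviations of equally numbered arrays correlated with r = 0.055 over all probe sets, 0.12 over the brighter ones and 0.21 in the authors' RMA table, and the labels name no batch. Leaving out 1 array gave 487 to 1197 higher and 643 to 1429 lower, where the lone array is assumed to vary like the other group. In the fits without a DMSO array the prior degrees of freedom were infinite, so each probe set was given the trend variance alone. The overlap of 1425 with the authors' table became 506 at an adjusted p under 0.01, and 0 by the ordinary test and without a trend. Of the lists, 8 were higher and 5 lower, and with fry 5 and 4. With an estimated correlation they were 0 and 0. In the simulation this setting also called 0% of the lists of independent genes shifted by 0.5. Spike-in centring (added) gave 5 and 8, and the G2/M, heat shock and ribosomal protein lists lost the call. The JAK-STAT, glycolysis and oxidative phosphorylation lists then passed as lower, with medians of -0.46, -0.56 and -0.40 against -0.41 over all probe sets. Lists also lost their call with camera on ranks (heat shock, metallothioneins, fatty acid synthesis), fry (metallothioneins, cholesterol, ribosomal proteins, histones), the filter on dim probe sets (fatty acid synthesis, histones), the mean of all probe sets of a gene (metallothioneins, fatty acid synthesis), median centring (fatty acid synthesis), log2(signal + 50) (added; fatty acid synthesis) and quantile normalization (ribosomal proteins). The replicate block changed the call of no list that passed, and with it the endoplasmic reticulum chaperone and T cell receptor lists passed too (adjusted p = 0.044 for each). Quantile normalization gained the endoplasmic reticulum chaperone and glycolysis lists, the filter on dim probe sets the T cell receptor and cytokine lists, and the mean of all probe sets of a gene the proteasome list. Leaving out 1 array gave 7 to 9 higher and 4 to 8 lower. Of 95 named genes past the threshold, 81 lost the call with median centring, 38 with spike-in centring (added), 36 without NC1153 replicate 1, 19 without NC1153 replicate 2, 18 without DMSO replicate 1, 14 without DMSO replicate 2, 11 with quantile normalization, 7 with log2(signal + 50) (added), and all 95 without a trend and by the ordinary test. The causes of these changes were not tested. Signals near background limit the size of the largest rises and of 4 of the 12 largest falls.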

Other observations

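The lists and tests of this part were chosen after the called genes had been seen, so their counts describe these arrays and are no independent evidence. Of 26 genes of mitochondrial RNA processing and protein import, 12 fell with NC1153, none rose and 14 did not pass. TRMT10C, a subunit of mitochondrial RNase P, fell by 1.55 on the log2 scale (adjusted p = 0.0011), TIMM21 by 1.40 and the assembly factor gene NDUFAF4 by 1.36. Of 20 nucleotide synthesis genes 8 fell and 12 did not pass, with falls of 1.57 for PNP, 1.22 for DHODH and 1.01 for UMPS besides CAD.

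Of 14 targets and feedback inhibitors of the ERK pathway, 6 fell, including ETV5 by 1.12, SPRED2 by 1.02 and DUSP5 by 0.94 besides DUSP6 and IER3. Another probe set of opposite sign exists for ETV5, SPRED2 and UMPS. Of 16 antigen processing and MHC class I genes, 3 fell: the immunoproteasome genes PSMB8 by 1.06 and PSMB9 by 0.94, and the peptide transporter gene TAP1 by 1.02. Genes called higher were more often non-coding than those called lower: 36 long non-coding RNAs and pseudogenes rose and 14 fell, against 574 and 548 protein-coding genes (Fisher's exact test, two-sided, p = 0.0038, which treats genes as independent). Among brighter genes, the median log2 change of long non-coding RNAs was 0.29 within replicate 1 and -0.064 within replicate 2, that of pseudogenes 0.31 and 0.14 and that of protein-coding genes 0.068 and -0.015.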
